A study of Penicillium oxalicum with 9 samples.

How the data were processed

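RNA from mycelium of Penicillium oxalicum, a filamentous fungus that secretes plant polysaccharide degrading enzymes, was extracted with TRIzol and sequenced on an Illumina instrument, per the labels' protocols. The 9 libraries fall into 3 groups of 3 by the strain given in the labels: Ku70, which lacks a gene of the non-homologous end joining pathway and serves as the control, MuPOX01907 and MuPOX08340. The libraries of a group carry the letters F, S and T. No label says that they came from separate cultures, so p-values measure only the spread between these libraries, which could be technical.

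Each deposited file lists the same 9834 gene IDs with an expected count and an FPKM value. The expected counts, named so per the file headers, are estimated reads per gene. They ranged from 14412296 to 14802260 in total per library, and between 97.1% and 97.8% of them were whole numbers within a tolerance of 1e-06. The FPKM values are fragments scaled to gene length and library size, as the name FPKM in the file headers states, and were used as deposited. Per the submitters' processing notes, BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2 were used. Their roles, the genome build and the annotation are not given in the sources used here. How reads shared by near-identical genes were split is likewise not given in the sources used here, and neither is the strandedness of the libraries. Genes with close copies and genes that overlap on opposite strands therefore carry an uncertainty that the errors printed here leave out.

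The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The test fixed in this way was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) of the FPKM values as deposited. Genes entered with a mean FPKM of at least 1 over the 9 libraries, which left 8589 genes and removed 1245. All 3 groups shared 1 estimate of the spread per gene. P-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called where the adjusted p was under 0.05 and the absolute log2 fold change was at least 1. Log2 fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low values, whereas folds are ratios of group mean FPKM. As the files also held expected counts, edgeR 4.0.16 with its quasi-likelihood test and DESeq2 1.42.0 were run on the expected counts rounded to whole numbers, and the edgeR counts of called genes stand beside those of limma. An adjusted p that DESeq2 gave as NA stayed NA.

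On simulated data with 200 changed genes, limma recovered 86.7%, 88.9% and 88% of the genes changed 4-fold in the settings of MuPOX01907 against Ku70 (8542 genes run), MuPOX08340 against Ku70 (8590 genes) and MuPOX01907 against MuPOX08340 (8473 genes). Of the genes changed 2-fold it recovered 23%, 27.6% and 26.5% by adjusted p in the same order. With the fold minimum limma called 6, 4 and 4 unchanged genes, edgeR 4, 2 and 4 and DESeq2 24, 23 and 16. DESeq2 recovered 94.9%, 92.9% and 93% of the 4-fold and 55%, 48% and 52% of the 2-fold changes. EdgeR recovered 88.8%, 86.9% and 87%, and 25%, 28.6% and 26.5%. The planted changes were balanced in direction, so no shift of the median was simulated. The simulation therefore does not show how many false calls unscaled FPKM give where the median shifts.

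The files do not pair the IDs with gene names. None of the 9834 IDs matched a table of RefSeq genes of assembly ASM172317v3 (0 matches). Locus tags of that table with the same running number had lengths unrelated to those implied by the files (correlation 0.0095 across 7490 genes, which are not independent replicates), so neither names nor coordinates were taken from it. Of 24 gene lists fixed in advance, those that needed product names were dropped. The 4 that remained rest on IDs recalled from the literature on strain HP7-1 of this fungus, and not on the files: 2 starch enzyme genes, 8 cellulase genes, 3 xylanase genes and the regulator gene POX03446 (PoxRsrA). Named genes were the IDs in the labels and these lists and, per comparison, the 2 IDs with the largest rise and the 2 with the largest fall in log2 fold change among called genes whose libraries did not overlap between the groups and whose higher group averaged at least 10 FPKM. As no cellulase or xylanase ID was called by limma, the examples given are those with the largest absolute log2 fold change. The cellulase list alone had the 5 tested members set as the minimum for camera, run with a preset correlation of 0.01 and adjusted over 3 comparisons, and for fry.

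Where a gene had few counts, the ratio of its summed counts was given with an exact binomial 95% interval, and a sum of 0 was replaced by a floor of 3 counts over the group. These intervals and floors cover counting error only. Overlap of calls between both mutants was set beside 50 simulated draws of unchanged groups. Each draw replaced every library, Ku70 included, by the Ku70 mean of each gene plus noise of the spread of its group. Both simulated mutants were set against the same simulated Ku70 libraries. The real Ku70 libraries were too few to be split into parts of 2. Pairs of consecutive ID numbers called in the same direction were counted and compared with 10000 permutations of the calls.

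The letters were checked for pairing through the correlation, across genes, of same-letter deviations from the group means. Against Ku70 it was -0.064, -0.062 and 0.089 for F, S and T of MuPOX01907 and 0.052, -0.17 and 0.26 for those of MuPOX08340. Between both mutants it was 0.58, 0.10 and 0.47, above the minimum of 0.1 for all letters, though with 0.101 only just so for S. By the rule set beforehand the letters counted as paired between the mutants and not with Ku70. This reading comes from these values and not from the labels. Deviations within a group cancel out, so the letters are not separate checks, and MuPOX01907 S correlated best with MuPOX08340 T. Those within Ku70 include the deviations of Ku70 F, which stood apart, so a pairing with Ku70 could have been missed.

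The alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, rescaling, centring, quantile normalization and a TMM-like scaling of FPKM, limma without the trend or with robust hyperparameters, fits on 2 groups, the letter as a replicate block, no fold minimum, an adjusted p under 0.01, edgeR, DESeq2, and leaving out each library in turn. Those that combine the omission of Ku70 F with edgeR or with TMM-like scaling, the fit of both mutants alone with the block, and the cellulase set tests with an estimated correlation without Ku70 S or Ku70 T, were added after seeing the data.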

Results

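Transcript levels were measured by RNA sequencing in mycelium of Penicillium oxalicum after 24 h of culture, in order to explore what transcription factors that govern amylase genes do. The strains were Ku70, the control, and mutants of the genes POX01907 and POX08340, named MuPOX01907 and MuPOX08340, with 3 libraries each. Sample titles place both mutants in 1% starch medium and Ku70 in 1% Avicel, a microcrystalline cellulose, while the growth protocol attached to all 9 libraries names Avicel. Strain and stated medium therefore go together in both comparisons with Ku70. Expected counts totalled between 14412296 (MuPOX08340 S) and 14802260 (Ku70 F) per library.

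Libraries of a group resembled each other to different degrees. Across genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) ranged from 0.978 to 0.995 within the mutants and was 0.985 between Ku70 S and Ku70 T. For Ku70 F it was 0.918 with Ku70 S and 0.909 with Ku70 T. Ku70 F held 92 IDs at least 8-fold above both other Ku70 libraries and 65 at least 8-fold below both, among IDs reaching 10 FPKM. The remaining libraries held at most 2 above and 4 below. No pair of libraries matched within sampling noise, the lowest chi-square per degree of freedom being 16 for MuPOX01907 S and T.

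The transcripts of both targeted genes were at or near the floor in their own mutants. POX01907 had 5 reads in all in the MuPOX01907 libraries, against 4613 in Ku70 and 5207 in MuPOX08340, a level 916-fold below Ku70 (95% interval 392 to 2820, exact binomial) and 1050-fold below MuPOX08340 (449 to 3230). As 3 of these 5 reads were in MuPOX01907 T, the ratio of mean FPKM was 941 against Ku70 with all libraries and 1882 without MuPOX01907 T, and 1075 and 2151 against MuPOX08340. POX08340 had 0 reads in the MuPOX08340 libraries, against 2759 in Ku70 and 666 in MuPOX01907, so that its level was at least 907-fold lower than in Ku70 and at least 221-fold lower than in MuPOX01907. The POX08340 transcript also fell in MuPOX01907, from 32.3 ± 2.92 FPKM (SD, n = 3) in Ku70 to 7.85 ± 0.509 (n = 3), a 4.12-fold difference (log2 -1.91, SE 0.129, limma adjusted p = 2.2e-05). POX01907 measured 21.5 ± 2.37 FPKM in MuPOX08340 and 18.8 ± 3.52 in Ku70, a difference that did not pass the test (log2 0.19, SE 0.159, limma adjusted p = 0.432).

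**Figure D1:**
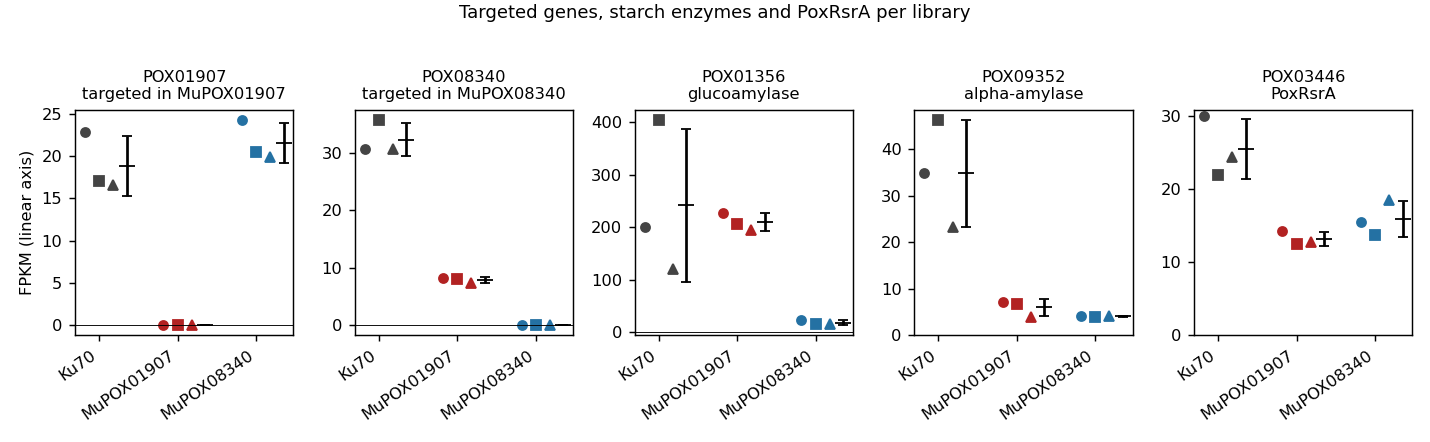
FPKM on linear axes of both targeted genes, the starch enzyme genes POX01356 and POX09352 and the regulator gene POX03446, with circles for F, squares for S and triangles for T libraries and bars for the mean and SD of 3 libraries per group. POX01907 averaged 0.02 FPKM in MuPOX01907 and POX08340 was 0 in MuPOX08340, while POX01356 lay between 15.4 and 23.8 FPKM in MuPOX08340 and at 121 or more in the other 6 libraries.

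In MuPOX01907 against Ku70, where the loss of POX01907 cannot be separated from the stated medium, 1 of the 2 starch enzyme genes was called. POX09352, known from the HP7-1 literature as the alpha-amylase gene Amy13A, fell 5.8-fold from 34.8 ± 11.5 to 6.00 ± 1.76 FPKM (SD, n = 3; log2 -2.34, SE 0.268, limma adjusted p = 0.000295). POX01356, which encodes the raw-starch-digesting glucoamylase PoxGA15A in that literature, measured 210 ± 17.0 FPKM in MuPOX01907 and 242 ± 146 in Ku70 and did not pass the test (log2 -0.03, SE 0.379, adjusted p = 0.947). In Ku70 it ranged from 121 to 404 FPKM, and its sign turned under TMM-like scaling (log2 0.28) and without Ku70 S (log2 0.42). The same count of 1 was called lower when adjusted over the list alone, and whether the 2 genes differed in their response was not tested. POX03446, encoding the starch enzyme regulator PoxRsrA, measured 13.2 ± 0.949 against 25.5 ± 4.08 FPKM, a log2 difference of -0.90 (SE 0.158, adjusted p = 0.00235) that stayed under the fold minimum.

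The largest rises in MuPOX01907 were those of POX08689, from 6.34 ± 6.25 to 8715 ± 309 FPKM (log2 10.77, SE 0.697, limma adjusted p = 1.92e-05), and POX08688, from 0.667 ± 0.320 to 807 ± 47.3 (log2 8.94, SE 0.166, adjusted p = 1.61e-08). The largest falls in log2 fold change were those of POX01695, from 3413 ± 886 to 46.1 ± 12.4 FPKM (74.1-fold, log2 -6.18, SE 0.274, adjusted p = 2.8e-06), and POX09025, from 198 ± 27.3 to 2.29 ± 0.472 (86.5-fold, log2 -5.92, SE 0.159, adjusted p = 1.48e-07). What these IDs encode is not given in the sources used here. By the ratio of mean FPKM, POX07173 fell further (184-fold, log2 -5.60, limma adjusted p = 0.00578), as did POX01907 itself (941-fold). POX08688 and POX08689 belong to a run of 8 consecutive IDs, POX08686 to POX08693, all called higher, with log2 fold changes from 6.26 to 10.77. The value of POX08689, the upper end of that range, was 9.80 without Ku70 F and 11.50 without Ku70 T. The run was singled out after its values were seen. It took between 3.64% and 4.14% of all counts in the MuPOX01907 libraries and at most 0.0235% in the other 6.

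**Figure D2:**
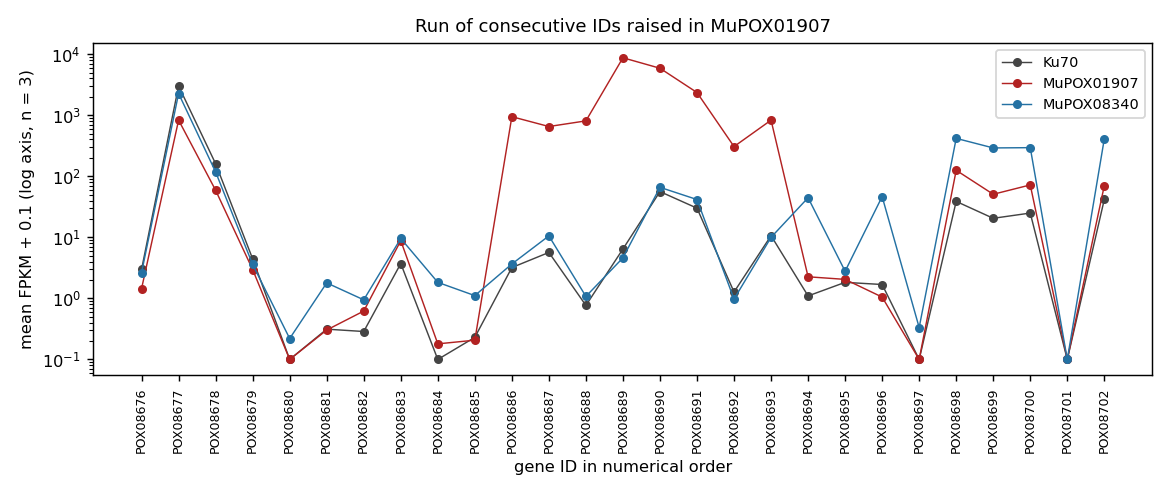
Mean FPKM plus 0.1 on a log axis (n = 3 per group) of consecutive IDs from POX08676 to POX08702 in numerical order. From POX08686 to POX08693 the MuPOX01907 means lay between 306 and 8715 FPKM, whereas those of Ku70 and MuPOX08340 were at most 65.8.

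Across the 8589 genes tested, limma called 485 higher and 1228 lower in MuPOX01907 than in Ku70, and edgeR 808 and 1066, with 1401 genes called in the same direction by both. Of the limma calls, 141 higher and 298 lower changed at least 4-fold on the log2(FPKM + 1) scale. The genes called higher took 22.9% ± 0.877 of the counts in MuPOX01907 (SD, n = 3) and 6.06% ± 1.19 in Ku70. The genes called lower took 4.08% ± 0.302 and 16.4% ± 1.33. The split of the calls by direction rested on the scaling: the median log2 fold change of all genes was -0.29 with FPKM as deposited and -0.01 after TMM-like scaling, which gave 812 higher and 754 lower and moved the share of higher calls from 28.3% to 51.9%. Centring gave 844 and 687 (55.1% higher) and quantile normalization 718 and 650 (52.5% higher). Of the 1713 genes called, 1239 were called in the same direction after TMM-like scaling. Without Ku70 F, the library that stood apart, the counts were 477 and 1351.

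In MuPOX08340 against Ku70, where the mutation of POX08340 likewise cannot be separated from the stated medium, both starch enzyme genes fell. The glucoamylase gene POX01356 fell 13.1-fold to 18.5 ± 4.59 FPKM (SD, n = 3; log2 -3.49, SE 0.379, limma adjusted p = 0.000887), and 8.69-fold without Ku70 S. The alpha-amylase gene POX09352 fell 8.5-fold to 4.10 ± 0.156 FPKM (log2 -2.76, SE 0.268, adjusted p = 0.000483). Both were also called when adjusted over the list alone. POX03446 measured 15.9 ± 2.47 FPKM, a log2 difference of -0.64 (SE 0.158, adjusted p = 0.0323) under the fold minimum.

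The largest rises in MuPOX08340 were those of POX08108, from 0.203 ± 0.135 to 74.7 ± 6.69 FPKM (log2 5.98, SE 0.166, limma adjusted p = 4.96e-07), and POX03632, from 1.84 ± 1.44 to 107 ± 8.07 (58.2-fold, log2 5.38, SE 0.355, adjusted p = 7.39e-05), the latter 98.6-fold without Ku70 F. Apart from that of POX08340 itself, the largest fall was that of POX05360, from 818 ± 188 to 19.1 ± 4.41 FPKM (42.9-fold, log2 -5.35, SE 0.199, adjusted p = 3.94e-06). POX05360 also fell in MuPOX01907, to 63.6 ± 0.70 FPKM (12.9-fold, adjusted p = 6.92e-06). POX09358, singled out after its values were seen for its abundance in Ku70 (9257, 29076 and 28047 FPKM in F, S and T), fell to 647 ± 115 FPKM in MuPOX08340 (log2 -4.94, adjusted p = 0.00026) and to 4752 ± 1124 in MuPOX01907 (log2 -2.07, adjusted p = 0.00451).

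In this comparison limma called 214 genes higher and 305 lower, and edgeR 222 and 433, with 500 called in the same direction by both. Of the limma calls, 78 higher and 70 lower changed at least 4-fold on the log2(FPKM + 1) scale. The genes called higher took 4.17% ± 0.00677 of the counts in MuPOX08340 (SD, n = 3) and 1.32% ± 0.340 in Ku70, and those called lower 1.56% ± 0.140 and 7.72% ± 0.661. Without Ku70 F the counts were 230 and 395. These counts depended on single libraries: the higher calls numbered 114 without MuPOX08340 S, 136 without MuPOX08340 T, 365 without MuPOX08340 F and 379 without Ku70 T, and the lower calls 153 without MuPOX08340 S and 156 without MuPOX08340 T. A fit on these 2 groups alone gave 117 higher and 155 lower.

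Between both mutants, whose titles state the same medium, the glucoamylase gene POX01356 was 11.3-fold higher in MuPOX01907 (log2 3.46, SE 0.379, limma adjusted p = 0.000234), while the alpha-amylase gene POX09352 did not pass the test (6.00 ± 1.76 against 4.10 ± 0.156 FPKM, n = 3 each, log2 0.42, SE 0.268, adjusted p = 0.223). The difference in POX01356 between the mutants was thereby itself tested, and 1 of the 2 starch IDs was called higher, also when adjusted over the list alone. POX03446 differed by a log2 of -0.25 (SE 0.158, adjusted p = 0.219), the sign of which turned under TMM-like scaling (0.07). The largest rises in MuPOX01907 relative to MuPOX08340 were again those of POX08689 (log2 10.63, SE 0.697, adjusted p = 1.85e-05) and POX08688 (log2 8.68, SE 0.166, adjusted p = 2.07e-08). The largest falls in log2 fold change were those of POX07173, at 1.44 ± 0.412 against 614 ± 27.9 FPKM (log2 -7.99, SE 1.2, adjusted p = 0.00112), and POX07270, at 2.84 ± 0.527 against 345 ± 65.2 (log2 -6.48, SE 0.411, adjusted p = 1.69e-05). In Ku70 these IDs measured 265 ± 223 and 48.3 ± 27.1 FPKM, with POX07173 at 9.53 FPKM in Ku70 F and at 363 and 422 in S and T.

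Limma called 535 genes higher and 1112 lower in MuPOX01907 than in MuPOX08340, and edgeR 886 and 798, with 1290 called in the same direction by both. Of the limma calls, 151 higher and 285 lower changed at least 4-fold on the log2(FPKM + 1) scale. The genes called higher took 18.7% ± 0.328 of the counts in MuPOX01907 (SD, n = 3) and 4.26% ± 0.160 in MuPOX08340, and those called lower 3.92% ± 0.114 and 13.9% ± 0.579. TMM-like scaling moved the median log2 fold change of all genes from -0.34 to -0.03 and gave 828 higher and 655 lower, a share of higher calls of 55.8% against 32.5%. Centring gave 874 and 599 (59.3% higher) and quantile normalization 769 and 619 (55.4% higher). Of the 1647 genes called, 1190 were called in the same direction after TMM-like scaling. Without Ku70 F, which entered through the shared spread, the counts were 597 and 1188.

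The 8 cellulase IDs stood high in Ku70 F and low in the other 8 libraries. Their median was 1254 FPKM in Ku70 F, where they spanned 69 to 6193 FPKM and took 2.35% of the counts, against 1.56 and 1.92 FPKM in Ku70 S and T and 1.15 to 3.06 FPKM in the 6 mutant libraries. The 3 xylanase IDs had a median of 1405 FPKM in Ku70 F and of 18.5 to 25.9 FPKM in the other 8. The median log2 fold change of the cellulase list was -2.77 in MuPOX01907 and -2.997 in MuPOX08340 against Ku70, with all 8 members negative, and 0.27 between the mutants. Examples against Ku70 in MuPOX01907 were POX04786 (log2 -3.63, SE 2.41), POX01166 (-3.52, SE 2.50) and POX05587 (-3.44, SE 2.45). Limma called 0 of the 8 cellulase and 0 of the 3 xylanase IDs in each of the 3 comparisons, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05. EdgeR called 7 cellulase IDs and the xylanase IDs POX00063 and POX08484 lower in MuPOX01907 than in Ku70, POX04786 lower in MuPOX08340 than in Ku70 and 0 between the mutants, and DESeq2 gave no adjusted p for any of them. Between the mutants the 0 calls say little, because the spread was shared with Ku70 F. POX04786, for example, had an SE of 2.41 there too, at 2.21 and 1.01 FPKM. Without Ku70 F, limma still called 0 of these IDs between the mutants. EdgeR then called POX04786, POX07535 and POX06783 higher in MuPOX01907 than in MuPOX08340.

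As a set, the cellulase IDs did not pass camera in MuPOX01907 or MuPOX08340 against Ku70 or between the mutants (adjusted p = 0.656, 0.0654 and 0.225), with an adjusted p = 0.875 in each with an estimated correlation. That correlation was 0.989 with all libraries and -0.0122 without Ku70 F. Fry gave adjusted p = 0.426, 0.426 and 0.878. Without Ku70 F, 6 cellulase IDs were tested, their median in MuPOX01907 against Ku70 turned to 0.11, and camera gave adjusted p = 0.209, 0.572 and 0.146. Fry then gave adjusted p = 0.495, 0.495 and 0.189. Its test for changes in any direction gave unadjusted p = 0.532, 0.126 and 0.000226, the last between the mutants. In MuPOX08340 against Ku70 the list passed camera with the preset correlation without Ku70 S (median -4.60, adjusted p = 0.00475) and without Ku70 T (median -4.38, adjusted p = 0.00901), where Ku70 F was 1 of 2 Ku70 libraries. It did not pass there with an estimated correlation (adjusted p = 0.685 without Ku70 S and adjusted p = 0.673 without Ku70 T). Without Ku70 F, the xylanase gene POX06783 was called higher in MuPOX01907 than in Ku70 (log2 1.59, limma adjusted p = 9.77e-05), at 60.4 ± 9.95 FPKM (SD, n = 3) against 18.8 in Ku70 S and 19.5 in Ku70 T.

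**Figure D3:**
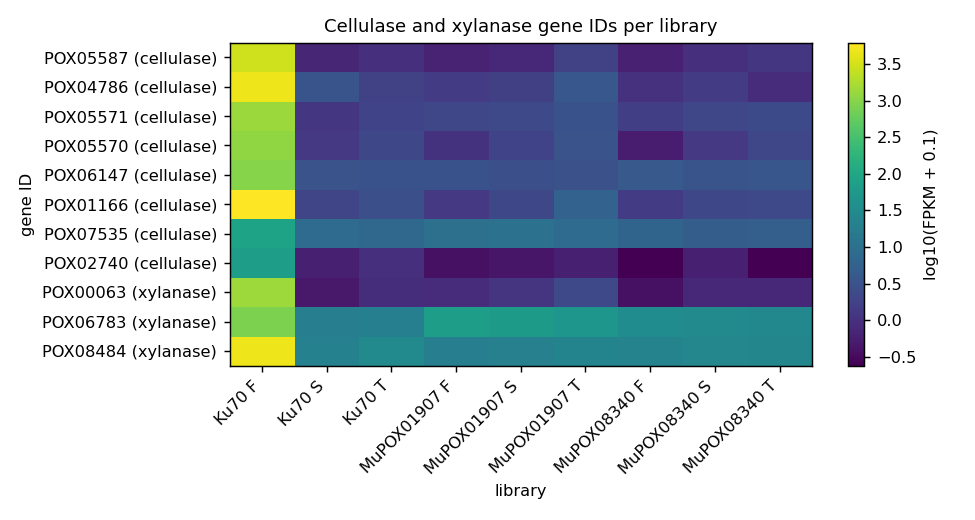
Colour scale of log10(FPKM + 0.1) for the 8 cellulase and 3 xylanase IDs in each of the 9 libraries. The Ku70 F column runs from 69 to 6193 FPKM, above every other library for each of the IDs.

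Of the genes called against Ku70, 29 were higher in both mutants, 189 were lower in both and 27 went opposite ways. Independent lists of these sizes would share 12.1 and 43.6 genes, and simulated unchanged groups, set against the same simulated Ku70 libraries, shared 5.04 and 4.06. The shared calls numbered 50 higher and 159 lower with TMM-like scaling, 52 and 159 after centring and 58 and 150 with quantile normalization, and edgeR gave 55 and 234. The fold changes of both comparisons had a Pearson correlation of 0.400 across genes, which are not independent replicates, against 0.841 in the simulation, and a covariance of 0.298 against 0.132. Part of the excess may come from the shared Ku70 libraries, as these were too few to be split, and the simulation left out any preparation shared by the mutants. Without Ku70 F the shared calls were 37 higher and 209 lower, and they numbered 71 and 290 without Ku70 T, 19 and 89 without MuPOX08340 S, 102 lower without MuPOX08340 T and 122 lower without Ku70 S.

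**Figure D4:**
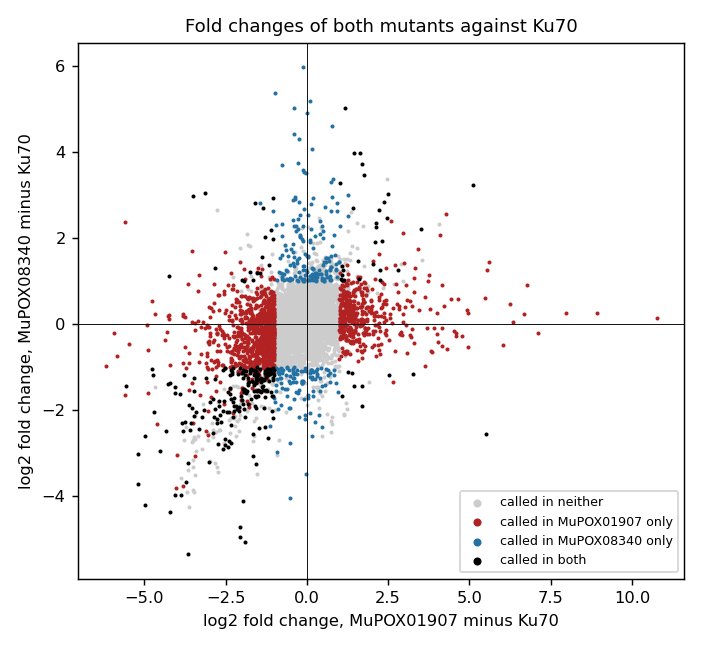
Log2 fold change against Ku70 of each of the 8589 genes tested, MuPOX01907 on the horizontal and MuPOX08340 on the vertical axis, coloured by the comparison in which a gene was called. The 189 genes called lower in both lie at the lower left and the 29 called higher in both at the upper right.

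Called genes lay at consecutive ID numbers more often than permuted calls. MuPOX01907 against Ku70 had 421 consecutive pairs called in the same direction, against a permuted mean of 182, MuPOX08340 against Ku70 had 77 against 14.5, and MuPOX01907 against MuPOX08340 had 356 against 159 (1-sided permutation p = 1e-04 in each, the smallest that 10000 draws can give). The longest runs, singled out after their values were seen, were POX08686 to POX08693 among higher calls in MuPOX01907 and 7 IDs from POX02063 to POX02069 among lower ones, whose median was 28.8 FPKM in MuPOX01907, 237 in Ku70 and 230 in MuPOX08340. In MuPOX08340 against Ku70 they were 7 IDs from POX05853 to POX05859 among higher calls (median 5.37 against 0.54 FPKM) and 5 IDs from POX09357 to POX09361 among lower ones (11.3 against 60.5 FPKM). Between the mutants, 11 IDs from POX05849 to POX05859 were lower in MuPOX01907 (median 0.317 against 4.36 FPKM). Whether consecutive numbers are neighbours on a chromosome was not tested.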

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

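The settings that combine the omission of Ku70 F with another choice, the fit of both mutants alone with the block, and the set tests with an estimated correlation without Ku70 S or Ku70 T, were chosen after the results had been seen. Called named genes kept their direction and their call under each setting that gave them an adjusted p, so that the limits lie in the counts, in the cellulase and xylanase IDs and in genes that were not called. The cause of a change was not tested unless stated. Low counts limited the IDs near the floor, such as POX01907 in MuPOX01907.

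In MuPOX01907 against Ku70 (485 higher, 1228 lower), higher calls numbered 844 after centring, 812 with TMM-like scaling, 808 with edgeR, 866 with DESeq2, and, without Ku70 F, 853 with edgeR and 814 with TMM-like scaling. Lower calls numbered 694 with a pseudocount of 5, 687 after centring, 650 with quantile normalization, 754 with TMM-like scaling and 809 with that scaling without Ku70 F. Without the fold minimum there were 1037 and 2957. In MuPOX01907 against MuPOX08340 (535 higher, 1112 lower), higher calls numbered 874 after centring, 828 with TMM-like scaling, 886 with edgeR, 941 with DESeq2, and, without Ku70 F, 978 with edgeR and 908 with TMM-like scaling. Lower calls numbered 681 with a pseudocount of 5, 599 after centring, 619 with quantile normalization, 655 with TMM-like scaling and 730 with that scaling without Ku70 F. Without the fold minimum there were 956 and 2994.

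In MuPOX08340 against Ku70 (214 higher, 305 lower), the counts were 117 and 155 in a fit on these 2 groups, 108 and 145 at an adjusted p under 0.01, 330 and 538 with DESeq2 and 544 and 570 without the fold minimum. Lower calls numbered 193 with a pseudocount of 5 and 477 with edgeR without Ku70 F. Leaving out each library in turn gave 114 (without MuPOX08340 S) to 379 (without Ku70 T) higher and 153 (without MuPOX08340 S) to 434 (without Ku70 T) lower calls. Where this left a group with 2 libraries, the shared spread was used.

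Genes higher in both mutants (29) numbered 18 with a pseudocount of 5, 52 after centring, 58 with quantile normalization, 50 with TMM-like scaling, 17 with 2 groups, 149 without the fold minimum, 15 at 0.01, 55 with edgeR, 84 with DESeq2, and, without Ku70 F, 57 with edgeR and 54 with TMM-like scaling. Genes lower in both (189) numbered 116 with a pseudocount of 5, 93 with 2 groups, 381 without the fold minimum, 84 at 0.01 and 294 with DESeq2. Leaving out single libraries gave 19 to 71 and 89 to 290, the ends being MuPOX08340 S and Ku70 T.

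The signs that turned belonged to genes limma had not called. POX01356 in MuPOX01907 against Ku70 was 0.281 after centring, 0.277 with TMM-like scaling, 0.100 with edgeR, 0.108 with DESeq2, 0.244 with TMM-like scaling without Ku70 F and -0.44 (without Ku70 T) to 0.422 (without Ku70 S) with single libraries left out. POX03446 between the mutants was 0.097, 0.134, 0.065, 0.059 and 0.079 with centring, quantile normalization, TMM-like scaling, edgeR and DESeq2, and without Ku70 F 0.057 with edgeR and 0.062 with TMM-like scaling. POX08484 between the mutants was 0.085, 0.088, 0.060 and 0.064 with centring, quantile normalization, TMM-like scaling and edgeR, and without Ku70 F 0.062 and 0.057. Against Ku70 in MuPOX01907 without Ku70 F, edgeR and TMM-like scaling gave 0.176 and 0.084 for POX04786, 0.694 and 0.338 for POX01166, 0.045 and 0.054 for POX08484 and 1.984 and 1.914 for POX06783, which also turned after centring (0.122) and TMM-like scaling (0.113) of all libraries. In MuPOX08340, POX06783 gave 0.646 and 0.616. The values without Ku70 S and without Ku70 F, the ends of the range over left-out libraries, were -5.421 to 0.107 for POX01166 and -1.10 to 1.594 for POX06783 in MuPOX01907, -2.07 to 0.624 for POX06783 and -3.891 to 0.002 for POX08484 in MuPOX08340, and -4.301 to 0.107 for the cellulase list median in MuPOX01907.

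With the letter as a replicate block, the counts were 512 higher and 1229 lower in MuPOX01907 against Ku70, 274 and 324 in MuPOX08340 against Ku70 and 547 and 1131 between the mutants, where a fit on both mutants with the block called 1827 genes. The block ended no call of a named gene and moved no count by over 1.5 times. MuPOX01907 S correlated best with MuPOX08340 T, so not every library matched its own letter.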

Other observations

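Tests on Ku70 F and on the shared fold changes of both mutants were chosen only after the results had been seen, and so were the settings without Ku70 F that add edgeR or TMM-like scaling.

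Of the 9 IDs numbered just past the run POX08686 to POX08693, from POX08694 to POX08702, 6 were called higher in MuPOX08340 than in Ku70. POX08694 reached 44.4 ± 12.7 FPKM (SD, n = 3) against 0.997 ± 1.12 in Ku70 (log2 4.60, limma adjusted p = 0.000199), and POX08696 46.3 ± 13 against 1.59 ± 1.43 (log2 4.31, adjusted p = 0.000328). POX08698, POX08699, POX08700 and POX08702 averaged 417 ± 81.1, 291 ± 45.1, 294 ± 41.0 and 410 ± 47.4 FPKM in MuPOX08340 and 38.6 ± 15.3, 20.4 ± 11.9, 24.9 ± 15 and 41.7 ± 10.5 in Ku70, with limma adjusted p from 7.91e-05 to 0.00129 in that comparison. POX08698, POX08699 and POX08700 were also called higher in MuPOX01907 than in Ku70 (log2 1.75, 1.45 and 1.70, limma adjusted p = 0.00212, 0.0274 and 0.0126), and all 6 IDs were called lower in MuPOX01907 than in MuPOX08340. Of the others, POX08695 averaged 2.68 ± 0.627 FPKM in MuPOX08340 and 1.73 ± 0.508 in Ku70 and was not called, while POX08697, with at most 0.233 FPKM on average in any group, and POX08701, listed at 0, were not tested. The IDs POX05853 to POX05859, all 7 called higher in MuPOX08340 than in Ku70, were called lower in MuPOX01907 than in MuPOX08340 in all 7 cases as well. These IDs were singled out after their values were seen, and what they encode is not given in the sources used here.

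Without Ku70 F, edgeR called the cellulase ID POX05571 and the xylanase ID POX06783 higher in MuPOX01907 than in Ku70. It called POX04786 (log2 1.46, adjusted p = 0.0315), POX07535 (1.17, adjusted p = 0.000796) and POX06783 (1.34, adjusted p = 0.000119) higher in MuPOX01907 than in MuPOX08340. In the limma fit without Ku70 F, POX06783 was the 1 cellulase or xylanase ID called, in MuPOX01907 against Ku70. With TMM-like scaling added, limma called POX06783 there too. Between the mutants it then called POX07535 (log2 1.03, adjusted p = 0.000602) and POX06783 (1.30, adjusted p = 0.000116) higher in MuPOX01907, but not POX04786. The limma fit of both mutants alone with the block called 0 cellulase and 0 xylanase IDs.

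Ku70 F departed from Ku70 S and T at 92 IDs above and 65 IDs below both. A minor admixture of RNA from another culture would lower a gene by no more than the replaced share, and the 65 IDs at least 8-fold below both libraries argue against it. The library was not one of the mutants, since the lower of its expected counts for POX01907 and POX08340 was 876. The cellulase IDs lay 8.75 log2 units above the higher of Ku70 S and T (median of 8), as a difference in carbon source or growth state within the Ku70 group could give, although this was found in the same data. Which of the Ku70 libraries matches the stated Avicel medium, whether a culture from outside the series was sampled, and any biological variation between Ku70 cultures stay open.

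The lower median of MuPOX01907 against Ku70 (log2 -0.29) coincided with genes called higher that took 22.9% of its counts, against 6.06% in Ku70. The genes called lower took 4.08% of the counts in MuPOX01907 and 16.4% in Ku70, which offset most of that gain. Both sets were picked by their direction in these same data. If the genes called higher had displaced other reads alone, genes of all levels should have shifted alike. The tertile medians of genes averaging at least 5 FPKM were -0.49, -0.29 and -0.02 from low to high, a range of 0.469. Bootstrap errors over genes were at most 0.019 and do not measure the spread between libraries. The tertiles were cut on means that include MuPOX01907, which can itself give such a trend. The range therefore does not decide whether a uniform shift was the whole cause. In MuPOX08340 against Ku70 the tertiles also differed, from -0.06 to 0.17, so the trend with level was not confined to MuPOX01907. In MuPOX01907 against MuPOX08340 they were -0.45, -0.37 and -0.22 from low to high, all negative. A part played by composition and an effect of the mutation or of the stated medium may both contribute, and TMM-like scaling, which brings the median near 0 by construction, does not separate them.

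The fold changes of both mutants against Ku70 varied together, with a covariance that exceeded that of simulated unchanged groups by 0.166, against an SD of 0.0072 over the draws. The draws varied each gene independently, so this SD leaves out deviations that many genes of a library share, such as those of Ku70 F. Whether the shared Ku70 libraries alone account for the excess is therefore not decided. The simulation also left out a preparation shared by both mutants, whose letters met the pairing rule (correlations 0.581, 0.101 and 0.47), and that explanation was not tested. Without Ku70 F the excess was 0.162, so that library was not its main source. The shared Ku70 libraries and such a preparation stay open. A response to starch against Avicel, as the titles state, and an effect common to both mutations cannot be told apart, since the stated medium goes with the strain in Ku70 S and T too.

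The 6 libraries of a comparison allow 10 splits into groups of 3, so the share of splits as large as the real one cannot go below 0.1. In MuPOX01907 against Ku70 the real split called 1713 genes and the highest other 0, with 1 of 10 splits, the real one, reaching that number. In MuPOX08340 against Ku70 these values were 519 and 0, and between the mutants 1647 and 0, again with 1 of 10 splits each. The other splits of the mutants that parted all 3 same-letter pairs, as the real one does, likewise called 0. Each other split mixes libraries of both groups, so the difference between the groups enters the spread and lowers the calls. The 0 calls therefore do not measure how many calls would arise without a group difference.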
